A study of Homo sapiens with 12 samples.

How the data were processed

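RNA was measured by sequencing in DU145 and PC3, human prostate cancer cell lines derived from metastases, each as the parental line and as a subline selected for growth in docetaxel. Docetaxel is a taxane that stabilises microtubules and arrests dividing cells. Per the labels, the dose was raised stepwise, starting at 10 for DU145 and 0.5 for PC3, until the half-maximal inhibitory concentration reached 1800 for DU145 and 15 for PC3. The submitters write these values in nm/ml, a unit left as given because its meaning is not stated, so the doses of the lines are not compared further here. Each of the 4 groups had 3 libraries. Nothing in the labels says whether the 3 came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

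Per the labels' protocols, messenger RNA was selected with oligo(dT), fragmented and made into paired-end libraries whose second strand was marked with dUTP. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR without giving their order, and name the build hg18. The coordinates in the files are those of GRCh38 instead: of 37385 genes also found in a GENCODE table on that build, 23671 had the same start and end and 37377 overlapped. The program that counted reads, its strand setting and the annotation release are not given in the sources used here. Genes that overlap another gene are therefore uncertain, since reads of either strand may have been assigned to them. Of the genes described, this applies to ABCB1, ABCC10, BCL2L1, BNIP3, CD68, CDK14, CLDN12, CSPG4, CYP1B1, DKK1, ELF3, ENO2, EPHA2, GATA2, GPR27, HERPUD1, HLA-C, HSP90B1, HSPG2, IFIT2, IL24, ITGA1, JPH1, KCNK15, KRT8, KRT18, LOX, MSMP, MT-CO3, MTUS1, PEG10, PLAU, PMEPA1, RB1, S100A4, SCUBE3, SOX9, SREBF2, STARD4, STK11, TNFAIP3, TUBA1B, TUBA4A, TUBB, TUBB6, VIM and the readthrough genes. Tubulins, histones, HLA genes and ribosomal proteins also have near-identical copies or pseudogenes that may share reads.

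The authors deposited 1 table per sample with 38611 Ensembl genes, giving a whole-number count and an FPKM value for each gene. In the deposited tables the FPKM of a gene was its count times a factor per gene and sample total, to within 0.1% for all 17457 genes compared, and 71 genes had no FPKM. The counts per library summed to between 62513103 and 72530254. At mean counts from 5 to 10 the variance between the 3 libraries of a group averaged 7.72 to 8.49 times the mean over genes (median 6.13 to 6.69). Independent single counts would average about 1. The deposited counts are therefore not treated as independent molecules, and the floors below, which assume independent counts, may be too low. The lowest chi-square per gene between any pair of libraries in a group was 15.15, where independent single counts of 1 library would give about 1. Since the counts do not behave as independent, this cannot say whether the libraries of a group are distinct. The first library of resistant PC3 lay further from the others of its group than they did from each other, with a chi-square per gene of 42.05 and 42.22 against 19.53.

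The choices of comparisons, gene lists, tests and rule for named genes were made before the data were examined. They assumed FPKM tables tested with limma, with edgeR if counts were present, and edgeR was used because the files hold counts. Genes were filtered with filterByExpr, which left 24128, and libraries were scaled with TMM. A model with 1 mean per group over all 12 libraries, leaving 8 residual degrees of freedom, was fitted with edgeR 4.0.16 (estimateDisp and glmQLFit, both robust) in R 4.3.3. Contrasts were tested with edgeR's two-sided quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called changed at an adjusted p under 0.05, and the number with a change of at least 1 log2 unit is given beside it. The standard error of a log2 change was its size divided by the square root of F. Levels are CPM, counts divided by the TMM-scaled library total and multiplied by 1e6, as mean ± SD. For a gene with no counts in a group, the fold is a bound computed against a floor of 3 counts over the group. If molecules were each counted about 8 times, as the variance allows, such a bound would be too high by about that factor.

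Altogether 35 gene lists were tested in each line with camera from limma 3.58.1 at its preset correlation of 0.01, with p-values adjusted over the lists of a line. Camera with an estimated correlation and fry were run beside it. The lists described covered drug efflux transporters, neighbours of ABCB1 on 7q21, docetaxel metabolism and uptake, tubulin isotypes, microtubule-associated proteins, mitosis, DNA replication and S phase, apoptosis regulators, epithelial identity, mesenchymal identity, basal keratins and markers, the type I interferon response, MHC class I antigen presentation, NF-kB targets, stem cell markers, luminal genes, neuroendocrine markers, Notch and Hedgehog signalling, Wnt signalling, GATA2 and the IGF axis, receptor tyrosine kinases, NRF2 and glutathione, hypoxia and glycolysis, cholesterol and fatty acid synthesis, unfolded protein and amino acid stress, extracellular matrix proteases and adhesion, cytosolic ribosomal proteins and mitochondrially encoded genes. The others were replication-dependent histones as a sign of RNA quality and markers of leukocytes, of fibroblasts and smooth muscle, and of endothelium. GO and KEGG terms carried in the files, with 15 to 300 tested genes, were ranked in the same way.

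The genes named were, per line, the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups, up to 4 members of each list with the lowest adjusted p, and ABCB1, ABCC1, ABCG2, TUBB3, CDH1 and VIM whatever their result. Added to these were the 8 largest rises and 8 largest falls shared by the lines, the 8 largest differences each way among genes changed in opposite directions, and, between parental lines, genes known to be lost in 1 of the lines and the 5 largest differences each way. The 3 libraries of each group lay entirely beyond the other 3 for 172 of the 173 named calls in DU145, 178 of 179 in PC3 and 14 of 14 between the parental lines. The rule itself required this of the largest, shared and opposite changes, and list members were picked by lowest adjusted p. These shares therefore follow largely from the choice and are no separate support for the calls.

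The fit was tested on counts simulated for the 24128 genes from the parental means, the real library sizes and the fitted dispersions, with 200 genes of at least 100 counts changed. For DU145, 86% of 2-fold and 92% of 4-fold changes were recovered and 4.1% of calls were false. For PC3 the figures were 74%, 94% and 1.6%. With 8 counts written per molecule drawn, false calls made up 15.2% for DU145 and 4.4% for PC3, and 23.5% and 14.1% for the difference between the lines. The adjusted p-values may therefore be too small if the deposited counts repeat molecules. These draws used dispersions fitted to the deposited counts, which already hold the extra variance, and changed only 200 genes. The shares of false calls therefore do not carry over to the calls reported. Alternatives, run with edgeR, limma or DESeq2 1.42.0, covered pseudocounts of 0.1, 1 and 5 on FPKM, filters at an FPKM of 1 and 5, other scalings, single comparisons, a replicate block and leaving out each library in turn. With a library left out the filter was rerun and passed 25525 to 25590 genes, which changed the genes a list is set against. A call lost or gained in such a fit is therefore not traced to the library left out. Counts divided by 8, an FPKM filter of 1 within edgeR and leaving out mitochondrial genes were added after seeing the data. Figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes on the Y chromosome and XIST were not reported. Some other genes that met the rule for named genes, and 3 of the 35 lists, are not reported here.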

Results

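The transcriptomes of 12 libraries were measured by RNA sequencing, 3 each of parental DU145, docetaxel-resistant DU145, parental PC3 and docetaxel-resistant PC3. Library totals lay between 62513103 and 72530254 counts, and between 25695 and 26401 genes had a count above 0. The mitochondrial genome supplied 4.11% ± 0.17 (SD, n = 3) of counts in parental DU145, 7.08% ± 0.05 in resistant DU145, 5.82% ± 0.20 in parental PC3 and 3.50% ± 0.05 in resistant PC3. On principal components of the 12202 genes with at least 5 CPM, the first component (73.5% of variance) separated the lines. Component 2 (13.5%) separated parental from resistant PC3, and component 3 (10.3%) did so for DU145.

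**Figure D1:**
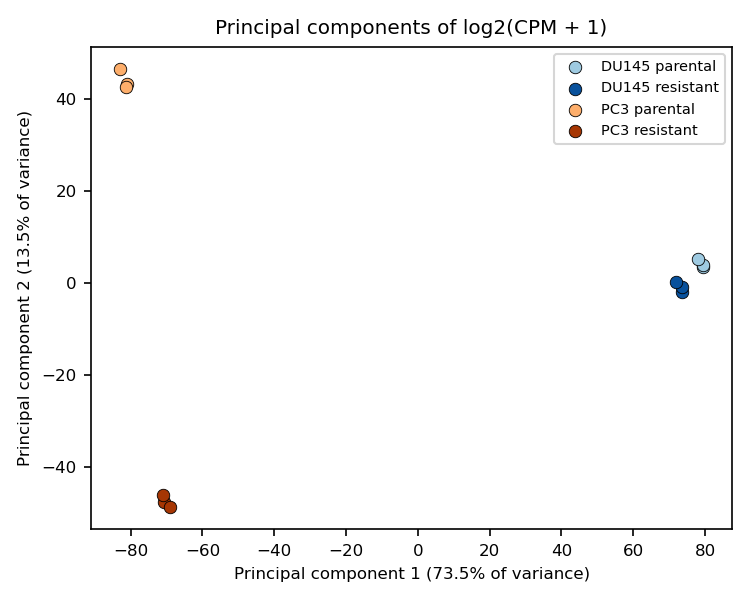
Scores of the 12 libraries on the first principal component (73.5% of variance) and the second (13.5%) of log2(CPM + 1) over 12202 genes, 1 point per library and 3 per group. DU145 libraries lie between 72.0 and 79.4 on the first axis and PC3 libraries between -82.9 and -69.0, and the second axis places parental PC3 at 42.7 to 46.6 and resistant PC3 at -48.8 to -46.2.

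The parental lines were compared to describe the backgrounds in which resistance was selected. CTNNA1, which links cadherins to actin and was fixed beforehand as lost in PC3, was 178-fold lower in parental PC3 (log2 difference -7.48 ± 0.09, SE). The cell cycle inhibitor RB1 (0.44 ± 0.08) and the kinase STK11 (0.62 ± 0.07), fixed as lost or mutated in DU145, were higher in PC3. MSMP, a secreted protein of the microseminoprotein family, showed 4267 CPM in parental PC3 and 0.147 in parental DU145, although it overlaps RGP1 and the counting strand is not stated. Genes without a count in parental DU145 included TCN1, a cobalamin-binding protein at least 8.36e+03-fold higher in PC3, SIDT1 (at least 3.55e+03-fold higher), the nitric oxide synthase NOS1 (at least 2.87e+03-fold) and the heparan sulfate sulfotransferase HS6ST2 (at least 2.84e+03-fold). In the other direction, GLB1L2, the lipid droplet protein LDAH and LINC02864 had no count in parental PC3 and were at least 2.53e+03-fold, 1.99e+03-fold and 1.5e+03-fold lower there. These and later bounds assume independent counts and may be too high by about 8-fold, the variance between libraries at low counts averaging about 8 times the mean. In all, 14561 of 24128 genes (60.3%) differed by the edgeR quasi-likelihood test, 7444 higher and 7117 lower in PC3, of which 8667 did so by at least 2-fold. The groups of 3 did not overlap for 67.7% of genes, where chance gives 10%.

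Resistant DU145 was set against its parental line to find what accompanied selection in docetaxel. ABCB1, the efflux pump P-glycoprotein that carries taxanes out of cells (ENSG00000085563, chromosome 7, 87503017 to 87713323, GRCh38), rose 100-fold from 0.707 ± 0.471 to 70.9 ± 6.91 CPM (SD, n = 3; log2 change 6.65 ± 0.54, adjusted p = 5.12e-06). The cell adhesion gene CDH1, which encodes E-cadherin (chromosome 16, 68737292 to 68835537), rose from 3.81 to 74.3 CPM (4.29 ± 0.31, adjusted p = 6.55e-07), and the desmosomal protein DSP rose 228-fold from 0.835 to 191 CPM. TUBB3, the class III beta-tubulin, rose 2.07-fold (1.05 ± 0.07) and VIM, the intermediate filament vimentin, fell by 0.21 ± 0.03 on the log2 scale. The transporters ABCC1 (-0.10 ± 0.05, adjusted p = 0.114) and ABCG2 (0.73 ± 0.78, adjusted p = 0.527) did not pass, although ABCC1 did without library 3 of resistant DU145 (-0.15). ABCB1 overlaps RUNDC3B on the opposite strand.

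The largest rises in DU145 began from almost no transcript. BEND4, CBLC, CNTN3, GPR27, PTPRO and SLC22A3 had no count in the parental libraries and were at least 538-fold, 567-fold, 958-fold, 486-fold, 746-fold and 475-fold higher in the resistant ones. CBLC is a ubiquitin ligase of the CBL family, CNTN3 a neuronal adhesion protein, PTPRO a receptor tyrosine phosphatase and SLC22A3 an organic cation transporter. MYH14, a nonmuscle myosin heavy chain, rose from 0.0205 to 26.9 CPM, BTBD11 from 0.0404 to 34.8, the zinc finger gene ZNF516 from 0.0154 to 17.6 and WFDC2 from 0.0103 to 6.96. Genes that fell to no count were TNS4, a focal adhesion protein (at least 1.48e+03-fold lower), RNF43, a ubiquitin ligase that removes Wnt receptors (at least 600-fold), and SDR16C5 (at least 397-fold). The synaptic adhesion gene NLGN1 fell from 6.91 to 0.0152 CPM, the neurotensin receptor NTSR1 195-fold, the kinase SYK 142-fold, the cytokine CSF2 112-fold and the basement membrane collagen COL4A4 63.8-fold. The readthrough genes RAB4B-EGLN2 (-8.94 ± 1.98) and POC1B-GALNT4 (-6.50 ± 1.57) also fell, but they share sequence with their component genes and are uncertain.

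Epithelial identity genes rose as a group in resistant DU145, with 18 of 24 higher, 2 lower and 4 not passing (21 called when adjusted over the list alone). Their median log2 change was 1.15 (camera adjusted p = 5.21e-12, and adjusted p = 0.0015 with an estimated correlation). Besides CDH1 and DSP, the tight junction protein CLDN1 rose 5.96-fold, the epithelial transcription factor ELF3 4.52-fold and the keratin KRT18, which overlaps KRT8, 1.96-fold. Of 30 mesenchymal genes, 16 fell, 5 rose and 9 did not pass (21 adjusted over the list alone), with a median of -0.98, or -0.95 without a member under the floor (camera adjusted p = 0.0115, but adjusted p = 0.21 with an estimated correlation). The matrix proteins FN1 and FBN1 fell 9.12-fold and 4.81-fold and the calcium-binding S100A4 3.25-fold, while the collagen chain COL6A2 rose 4.17-fold. Among 30 extracellular matrix protease and adhesion genes, 12 rose, 6 fell and 12 did not pass (20 adjusted over the list alone; median 0.32, camera adjusted p = 4.41e-10, and 0.0087 with an estimated correlation). The membrane-anchored metalloprotease MMP14 rose 16.2-fold (4.02 ± 0.05), the urokinase gene PLAU 6.84-fold and the hyaluronan receptor CD44 6.56-fold. PLAU overlaps C10orf55. In the stem cell and progenitor list 7 of 13 rose, 3 fell and 3 did not pass (11 adjusted over the list alone; median 1.17, camera adjusted p = 3.46e-08, and 0.0046 with an estimated correlation). The rises included the transcription factors SOX9 (20.7-fold) and KLF4 (2.76-fold) and the integrin ITGA2 (3.87-fold).

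Among the lists described, unfolded protein and amino acid stress fell most widely in DU145, with 19 of 22 genes lower, 2 higher and 1 not passing (22 adjusted over the list alone). The median was -1.03 (camera adjusted p = 6.62e-18, and adjusted p = 0.011 with an estimated correlation). The chaperones HSPA5 and HSP90B1 fell 2.79-fold and 3.17-fold, the disulfide isomerase PDIA4 2.86-fold and HERPUD1, which acts in degradation from the endoplasmic reticulum, 3.67-fold. All 13 mitochondrially encoded genes rose (13 adjusted over the list alone; median 1.03, camera adjusted p = 6.71e-32, and 0.0051 with an estimated correlation). Among them were the respiratory chain subunits MT-ND1 (3.01-fold) and MT-CO1 (2.04-fold), and with limma after quantile normalization the median was 0.44. NF-kB targets rose more often than they fell, 16 against 8 of 28 with 4 not passing (25 adjusted over the list alone; median 0.61, camera adjusted p = 3.92e-06, and 0.013 with an estimated correlation). The feedback inhibitors TNFAIP3 and NFKBIA rose 6.17-fold and 2.72-fold and the adhesion molecule ICAM1 3.89-fold, whereas the chemokine CXCL8 fell 6.40-fold.

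A further set of lists passed camera at its preset correlation in DU145 and did not with an estimated one. Mitosis and spindle checkpoint genes rose in 20 of 28 cases, with 1 fall (23 adjusted over the list alone; median 0.31, camera adjusted p = 3.17e-05, but adjusted p = 0.35 with an estimated correlation). The rises included the kinase AURKA (2.24-fold) and the ubiquitin-conjugating enzyme UBE2C (2.16-fold). The broader KEGG cell cycle term did not rise in DU145, with 33 of 123 genes higher and 38 lower (median -0.04, camera adjusted p = 0.98). Degradation by the anaphase-promoting complex, a GO term, passed at the preset correlation with 32 of 81 higher and 13 lower (median 0.06, camera adjusted p = 0.0416). MHC class I presentation genes rose in 13 of 20, with 4 falls (17 adjusted over the list alone; median 0.89, camera adjusted p = 2.04e-05, but adjusted p = 0.11 with an estimated correlation). HLA-C rose 2.67-fold and the loading factor TAPBP 1.89-fold, while the chaperone CALR fell 2.12-fold. TAP1, a member of this list, closes a run of 25 neighbouring chromosome 6 genes whose median change was 0.68. A rise of the list by function was not separated from a rise by region. Of 29 genes at 7q21, ABCB1 included, 14 fell, 3 rose with ABCB1 among them, and 12 did not pass (19 adjusted over the list alone; median -0.38, camera adjusted p = 0.00253, but adjusted p = 0.10 with an estimated correlation). Examples were AKAP9 (-0.85 ± 0.06), CLDN12 (-0.93 ± 0.07) and CDK14 (-1.11 ± 0.06). Microtubule-associated proteins fell in 16 and rose in 8 of 29 (25 adjusted over the list alone; median -0.26, mean 0.00, camera adjusted p = 0.00952, but adjusted p = 0.13 with an estimated correlation). MAP2 was 18.8-fold, MAP1A 6.57-fold and MAP4 1.73-fold lower and the end-binding protein MAPRE1 1.48-fold higher. NRF2 and glutathione genes fell in 14 and rose in 6 of 26 (21 adjusted over the list alone; median -0.21, camera adjusted p = 0.00319, but adjusted p = 0.21 with an estimated correlation). The reductases AKR1C3 and NQO1 were 6.73-fold and 2.43-fold lower. Hypoxia and glycolysis genes fell in 16 and rose in 6 of 27 (23 adjusted over the list alone; median -0.21, camera adjusted p = 0.0151, but adjusted p = 0.53 with an estimated correlation). BNIP3 was 1.98-fold lower and the hypoxia-inducible factor EPAS1 11.6-fold higher. Cytosolic ribosomal proteins rose in 20 and fell in 3 of 38 (23 adjusted over the list alone; median 0.16, camera adjusted p = 0.0271, but adjusted p = 0.82 with an estimated correlation).

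The call for cholesterol and fatty acid synthesis in DU145, where 17 of 28 genes fell and 6 rose (23 adjusted over the list alone; median -0.24, camera adjusted p = 0.0319, but adjusted p = 0.53 with an estimated correlation), was lost without the first parental or the second resistant DU145 library (adjusted p = 0.0568 in each case). STARD4, a sterol carrier, fell 2.93-fold and the sterol enzyme SQLE 1.66-fold. Docetaxel metabolism and uptake, with 3 of 7 genes higher and 1 lower (4 adjusted over the list alone; median 0.91, camera adjusted p = 0.0271, but adjusted p = 0.12 with an estimated correlation), lost its call without any of the 12 libraries in turn (adjusted p from 0.064 to 0.111). These fits also tested more genes, so the loss may come from the rerun filter and not from a library, which was not tested. Its members SLCO1B3, a hepatic uptake transporter of taxanes, and the oxidase CYP3A5 rose 5.06-fold and 1.88-fold, and GSTP1 fell by 0.18 ± 0.06 on the log2 scale, a call lost without the first parental or the first or second resistant library (adjusted p up to 0.182).

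The remaining lists did not pass camera in DU145, although single members changed. Of 11 efflux transporters, ABCB1, ABCC10 (1.63-fold) and ABCC3 (1.27-fold) rose, none fell and 8 did not pass (3 adjusted over the list alone; median 0.34, adjusted p = 0.385). Tubulin isotypes split into 5 higher, 3 lower and 8 not passing (9 adjusted over the list alone; median 0.12, or -0.03 with limma on log2(TPM + 1); adjusted p = 0.60). TUBB was 1.54-fold higher and TUBB6 1.47-fold lower. For DNA replication and S phase, 11 of 26 rose, 3 fell and 12 did not pass (14 adjusted over the list alone; median 0.11, or -0.03 with limma on log2(TPM + 1); adjusted p = 0.113). The list passed without parental DU145 library 1 or 2 or resistant PC3 library 2 or 3 (adjusted p from 0.0367 to 0.0492). Apoptosis regulators divided into 12 higher, 10 lower and 8 not passing (22 adjusted over the list alone; median 0.04, mean -0.19, test direction up, adjusted p = 0.996). The survival genes MCL1 and BCL2L1 were 2.24-fold and 1.58-fold higher. Interferon response genes divided into 13 higher, 15 lower and 9 not passing (29 adjusted over the list alone; median 0.04, mean 0.73, adjusted p = 0.44). IFIT2 was 14.9-fold and DDX60 11.6-fold higher and ISG15 6.97-fold lower. Among receptor tyrosine kinases and ligands 11 rose, 9 fell and 8 did not pass (22 adjusted over the list alone; median 0.07, mean -0.33, test direction up, adjusted p = 0.126). The receptor EPHA2 was 5.69-fold and EGFR 2.54-fold higher and the ligand EGF 14.1-fold lower. The GATA2 and IGF axis gave 5 higher, 5 lower and 3 not passing (10 adjusted over the list alone; median 0.20, adjusted p = 0.25). The binding protein IGFBP4 was 8.46-fold and the adaptor IRS1 6.53-fold higher. Basal markers gave 3 higher, 2 lower and 4 not passing (7 adjusted over the list alone; median 0.65, adjusted p = 0.379). The laminin chain LAMB3 was 5.64-fold higher and LAMA3 8.83-fold lower.

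Luminal genes in DU145 gave 3 higher, 2 lower and 8 not passing (5 adjusted over the list alone; median 0.00, or -0.03 without members under the floor, mean -0.11, test direction up, adjusted p = 0.945). PMEPA1 was 9.62-fold higher. Neuroendocrine markers gave 2 higher, 2 lower and 7 not passing (4 adjusted over the list alone; median -0.28, or -0.34 without a member under the floor; adjusted p = 0.547). PEG10 was 3.46-fold lower. Notch and Hedgehog genes gave 4 higher, 5 lower and 13 not passing (9 adjusted over the list alone; median -0.17, mean 0.17, test direction down, adjusted p = 0.96). The Notch target HES1 was 67.3-fold higher. Wnt signalling gave 9 higher, 8 lower and 10 not passing (18 adjusted over the list alone; median -0.07, mean -0.02, test direction up, adjusted p = 0.961). The secreted inhibitor SFRP1 was 84.1-fold higher and WNT7A 28.0-fold lower. Replication-dependent histones, which lack poly(A) tails and served as a sign of RNA quality, gave 2 lower and 10 not passing (1 adjusted over the list alone; median -0.36, adjusted p = 0.435). Markers of other cells gave 1 higher and 1 lower of 5 for leukocytes (2 adjusted over the list alone; median 0.01, mean -0.77, adjusted p = 0.961), 3 lower of 10 for fibroblasts and smooth muscle (2 adjusted over the list alone; median -1.40, adjusted p = 0.376), and 1 higher and 3 lower of 9 for endothelium (4 adjusted over the list alone; median 0.00, or -0.33 without a member under the floor, mean -0.36, adjusted p = 0.832). CTNNA1 fell, and RB1 and STK11 rose.

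In all, 9554 of 24128 genes (39.6%) changed in DU145 by the edgeR quasi-likelihood test, 4556 higher and 4998 lower, and 3135 of them by at least 2-fold (1735 higher, 1400 lower). With limma on log2(TPM + 1) over 15332 genes the split was 3155 higher against 6217 lower (33.7% higher, median of all genes -0.149), against 45.0% higher and a median of -0.033 with limma on log2(FPKM + 1) over the same genes. The groups of 3 did not overlap for 51.2% of genes, where chance gives 10%.

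**Figure D2:**
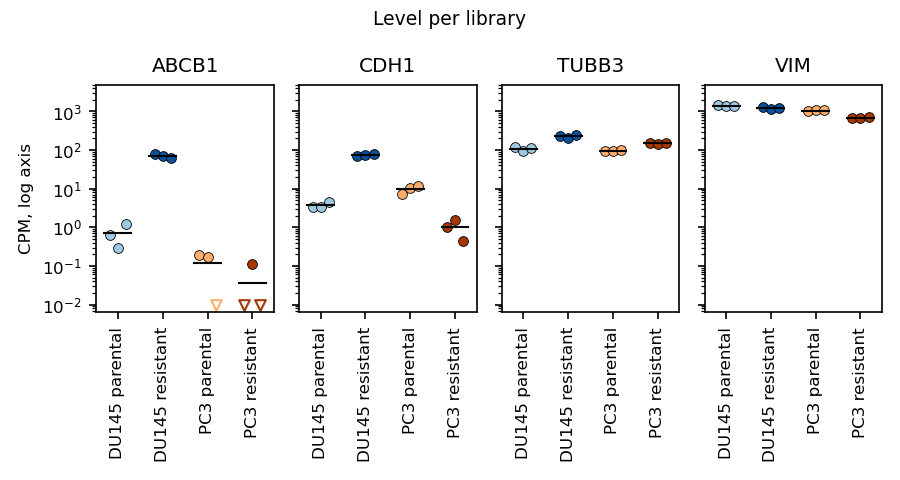
CPM on a log axis of ABCB1, CDH1, TUBB3 and VIM in each of the 12 libraries, by group, with bars at the group means and open triangles for libraries without a count. ABCB1 averages 70.9 CPM in resistant DU145 and at most 0.707 in the other groups, while CDH1 goes from 3.81 to 74.3 in DU145 and from 9.94 to 1.03 in PC3.

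Resistant PC3 was set against parental PC3 in the same way. ABCB1 was scarcely detected in either (0.121 and 0.0372 CPM; -1.75 ± 1.44, adjusted p = 0.384), and CDH1 fell from 9.94 to 1.03 CPM (-3.29 ± 0.33, adjusted p = 7.97e-06). TUBB3 rose 1.55-fold (0.63 ± 0.07) and VIM fell by 0.61 ± 0.03 on the log2 scale, while ABCC1 (0.00 ± 0.05, adjusted p = 1.0) and ABCG2 (-1.12 ± 1.28, adjusted p = 0.539) did not pass.

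Several genes abundant in parental PC3 fell to low levels in the resistant line. MSMP fell 2490-fold, from 4267 to 1.72 CPM, the gel-forming mucin MUC5B 577-fold from 231 to 0.394, and the mucus-associated FCGBP 479-fold from 337 to 0.709. The secreted SCUBE3 fell 251-fold from 256.5 CPM, NOS1 282-fold, the potassium channel KCNK15 243-fold, the prostaglandin synthase PTGS2 227-fold and the synaptic protein CPLX1 188-fold. SLC44A4 and UBE2QL1 fell to no count and were at least 351-fold and 358-fold lower. Among rises, ADAMTS14, a procollagen-processing protease, and ANKRD30A had no count in parental PC3 and were at least 423-fold and 327-fold higher. COX7B2 rose from 0.0197 to 7.35 CPM, NLRP10 from 0.0208 to 5.35, the transcription factor RUNX3 230-fold from 0.0788 to 19.2, the sialic acid receptor CD33 168-fold, the actin regulator COBL 121-fold, IL13RA2 98.3-fold and CCBE1 94.0-fold. IL24 (6.39 ± 1.09) overlaps FCMR and is uncertain.

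Mitosis and replication genes rose almost throughout in resistant PC3. Of 28 mitosis and spindle checkpoint genes, 27 rose and 1 did not pass (27 adjusted over the list alone; median 0.88, camera adjusted p = 1.80e-19, but adjusted p = 0.051 with an estimated correlation). Among them were the checkpoint protein MAD2L1 (2.52-fold), the cyclin CCNB1 (2.21-fold) and BIRC5 (2.00-fold). Of 26 replication and S phase genes, 24 rose, 1 fell and 1 did not pass (25 adjusted over the list alone; median 0.70, camera adjusted p = 3.45e-11, but adjusted p = 0.051 with an estimated correlation). Among them were GINS4 (2.98-fold), the helicase subunit MCM4 (2.23-fold) and the licensing factor CDC6 (2.20-fold). Of 16 tubulins, 9 rose, none fell and 7 did not pass (9 adjusted over the list alone; median 0.33, camera adjusted p = 0.00226, but adjusted p = 0.15 with an estimated correlation). TUBA1B was 2.68-fold, TUBA4A 2.33-fold and TUBB4B 1.71-fold higher.

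Epithelial identity genes fell in resistant PC3, 14 of 24 being lower, 5 higher and 5 not passing (19 adjusted over the list alone; median -0.61, camera adjusted p = 3.94e-04, and 0.029 with an estimated correlation). CLDN3 and CLDN1, proteins of tight junctions, fell 6.01-fold and 5.71-fold, and the keratins KRT8 and KRT19 3.66-fold and 1.65-fold. Extracellular matrix protease and adhesion genes rose in 17, fell in 8 and did not pass in 5 of 30 (26 adjusted over the list alone; median 0.35, camera adjusted p = 1.96e-08, and 0.029 with an estimated correlation). CD44 was 7.27-fold, PLAU 5.88-fold and the matrix protein TNC 3.61-fold higher and the collagen receptor ITGA1 12.2-fold lower. Stem cell and progenitor markers rose in 8, fell in 2 and did not pass in 3 of 13 (10 adjusted over the list alone; median 0.73, camera adjusted p = 1.89e-07, and 0.014 with an estimated correlation). The surface glycoprotein CD24 was 17.3-fold and the polycomb protein BMI1 1.66-fold higher and SOX9 4.72-fold lower.

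Several lists fell in PC3 by camera at the preset correlation alone. All 13 mitochondrially encoded genes fell (13 adjusted over the list alone; median -0.68, or -0.09 with limma after quantile normalization; camera adjusted p = 6.22e-12, but adjusted p = 0.051 with an estimated correlation), MT-CO3 by 2.28-fold and MT-ND1 by 1.78-fold. Cholesterol and fatty acid synthesis fell in 20 and rose in 2 of 28 (22 adjusted over the list alone; median -0.46, camera adjusted p = 2.25e-09, but adjusted p = 0.062 with an estimated correlation). The desaturase SCD was 6.50-fold and the sterol regulator SREBF2 2.90-fold lower. Hypoxia and glycolysis fell in 15 and rose in 6 of 27 (23 adjusted over the list alone; median -0.75, camera adjusted p = 1.04e-07, but adjusted p = 0.15 with an estimated correlation). The glucose transporter SLC2A1 was 3.62-fold, PFKFB3 2.86-fold and PFKP 2.22-fold lower. NF-kB targets fell in 14 and rose in 6 of 28 (21 adjusted over the list alone; median -0.32, camera adjusted p = 0.00242, but adjusted p = 0.051 with an estimated correlation). ICAM1 was 5.74-fold, the chemokine CXCL6 3.69-fold and the subunit NFKB2 2.60-fold lower. NRF2 and glutathione genes, by contrast, rose in 13 and fell in 4 of 26 (17 adjusted over the list alone; median 0.17, camera adjusted p = 0.00312, but adjusted p = 0.18 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, was 3.06-fold and thioredoxin (TXN) 2.47-fold higher.

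Luminal genes fell in 7 and rose in 3 of 13 in PC3 (12 adjusted over the list alone; median -1.39, camera adjusted p = 0.0120, but adjusted p = 0.062 with an estimated correlation). PMEPA1 fell 41.7-fold, NDRG1 3.14-fold and the pioneer factor FOXA1 2.63-fold. This call was lost without parental DU145 library 1 or 2 and without any of the 6 PC3 libraries (adjusted p from 0.0541 to 0.128). Receptor tyrosine kinases and ligands gave 12 higher, 9 lower and 7 not passing of 28 (22 adjusted over the list alone; median 0.26, mean -0.22, camera adjusted p = 0.0183 upward, but adjusted p = 0.062 with an estimated correlation), a call lost without any of the 12 libraries in turn (adjusted p from 0.151 to 0.303). The fits with a library left out also tested more genes, and whether that or the library cost the luminal and kinase calls was not tested. The growth factor TGFA rose 29.1-fold and the receptors AXL and EGFR 4.75-fold and 2.58-fold, and EPHB2 fell 14.9-fold.

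No other list passed camera in PC3. Efflux transporters gave 2 higher, 4 lower and 5 not passing of 11 (7 adjusted over the list alone; median -0.64, adjusted p = 0.0916). ABCC3 was 8.26-fold lower. The 7q21 genes gave 11 higher, 6 lower and 12 not passing (18 adjusted over the list alone; median 0.09, mean -0.14, test direction up, adjusted p = 0.52), and docetaxel metabolism and uptake 3 higher and 4 not passing (3 adjusted over the list alone; median 0.68, adjusted p = 0.334). In the latter, CYP1B1, which oxidises drugs and hormones, rose by 1.18 ± 0.42 but lost its call in 9 of the 12 fits with a library left out (adjusted p up to 0.158). The exceptions were library 3 of parental DU145, library 3 of parental PC3 and library 2 of resistant PC3. Microtubule-associated proteins gave 13 higher, 10 lower and 6 not passing (24 adjusted over the list alone; median 0.26, mean -0.03, test direction up, adjusted p = 0.164). The destabilising protein STMN1 was 2.23-fold higher and tau (MAPT) 3.63-fold lower. Apoptosis regulators gave 10 higher, 10 lower and 10 not passing (22 adjusted over the list alone; median 0.15, adjusted p = 0.759). CFLAR, which blocks death receptor signalling, was 1.82-fold lower. Mesenchymal genes gave 9 higher, 14 lower and 7 not passing (25 adjusted over the list alone; median -1.10, adjusted p = 0.0891). LOX, which crosslinks collagen, was 9.09-fold and the collagen chain COL6A1 5.10-fold lower. Basal markers gave 2 higher, 2 lower and 5 not passing (4 adjusted over the list alone; median -0.12, mean 0.46, test direction up, adjusted p = 0.0562). LAMB3 was 7.13-fold higher and KRT15 3.45-fold lower. Interferon response genes gave 9 higher, 18 lower and 10 not passing (29 adjusted over the list alone; median -0.60, adjusted p = 0.158), and passed without parental PC3 library 1 or 2 (adjusted p = 0.0411 and 0.04). IFI27 was 23.4-fold lower and SAMD9 2.90-fold higher. MHC class I genes gave 5 higher, 10 lower and 5 not passing (15 adjusted over the list alone; median -0.20, adjusted p = 0.0574).

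The GATA2 and IGF axis in PC3 gave 5 higher, 6 lower and 2 not passing (12 adjusted over the list alone; median -0.03, adjusted p = 0.641). The transcription factor GATA2 was 26.9-fold lower and IGFBP4 5.85-fold higher. Neuroendocrine markers gave 2 higher, 3 lower and 6 not passing (5 adjusted over the list alone; median 0.02, mean -0.70, test direction down, adjusted p = 0.944). ENO2 was 3.63-fold lower. Notch and Hedgehog genes gave 2 higher, 10 lower and 10 not passing (12 adjusted over the list alone; median -0.37, adjusted p = 0.072). They passed without resistant DU145 library 1 or 2 or parental PC3 library 2 (adjusted p from 0.0222 to 0.0432). The receptor NOTCH3 was 13.4-fold lower and NOTCH1 2.25-fold higher. Wnt signalling gave 8 higher, 10 lower and 9 not passing (18 adjusted over the list alone; median -0.03, or -0.08 without members under the floor, mean 0.22, test direction down, adjusted p = 0.478). The inhibitor DKK1 was 2.60-fold higher. Unfolded protein and amino acid stress gave 8 higher, 8 lower and 6 not passing (16 adjusted over the list alone; median -0.03, or 0.05 with limma on log2(TPM + 1); adjusted p = 0.259). ATF3 was 6.67-fold higher and DDIT4 4.83-fold lower. Cytosolic ribosomal proteins gave 16 higher, 4 lower and 18 not passing (21 adjusted over the list alone; median 0.03, or -0.14 with limma after quantile normalization and -0.01 both with limma on FPKM and in edgeR without TMM; adjusted p = 0.437). Histones gave 4 lower and 8 not passing (4 adjusted over the list alone; median 0.07, mean -0.32, test direction down, adjusted p = 0.395). Among markers of other cells, leukocytes gave 1 higher of 5 (0 adjusted over the list alone; median 1.09, adjusted p = 0.566). This was CD68, whose call was lost without library 2 of either DU145 group, library 2 or 3 of parental PC3 or any library of resistant PC3 (adjusted p up to 0.124). Fibroblasts and smooth muscle gave 3 lower of 10 (3 adjusted over the list alone; median -2.14, adjusted p = 0.072). This list passed in 9 of the 12 fits with a library left out (adjusted p from 0.00577 to 0.0411), the exceptions being library 2 of parental PC3 and libraries 1 and 2 of resistant PC3. Endothelium gave 2 higher and 4 lower of 9 (6 adjusted over the list alone; median -0.07, adjusted p = 0.114). The receptor KDR was 4.37-fold lower. CTNNA1 fell and RB1 rose, while STK11 did not pass.

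In all, 10615 of 24128 genes (44.0%) changed in PC3 by the edgeR quasi-likelihood test, 5405 higher and 5210 lower, and 4115 by at least 2-fold (1728 higher, 2387 lower). With limma on log2(TPM + 1) over 15332 genes the split was 5738 higher against 4097 lower (58.3% higher), against 4786 and 4989 with limma on log2(FPKM + 1) over the same genes. The groups of 3 did not overlap for 54.4% of genes, where chance gives 10%. Without the first resistant library, which lay apart from its group, 9881 genes were called. Camera at the preset correlation called 16 of 35 lists in DU145 and 13 in PC3, of which 6 and 3 passed with an estimated correlation, and fry, which asks only whether a list moves on balance 1 way, called 28 and 31.

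**Figure D3:**
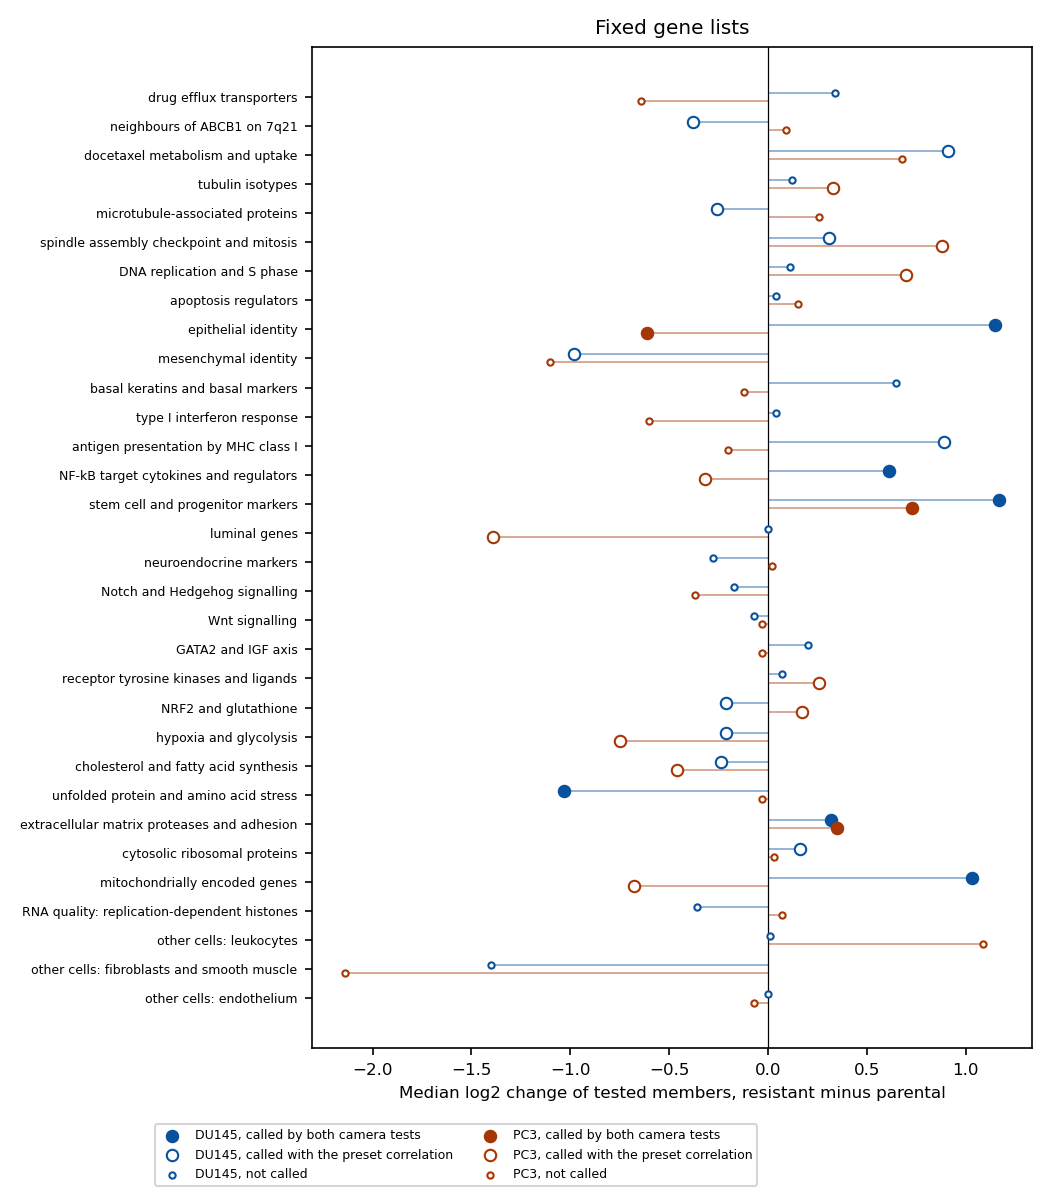
Median log2 change (resistant minus parental) of the tested members of each gene list described, in DU145 and in PC3, with filled points for lists called by camera with both the preset and the estimated correlation, large open points for the preset alone and small open points for lists not called. Epithelial identity stands at 1.15 in DU145 and -0.61 in PC3, and mitochondrially encoded genes at 1.03 and -0.68.

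The sublines were then compared to find which changes they shared. Genes that rose in both included STC1, a secreted glycoprotein (51.0-fold in DU145, 8.34-fold in PC3), the potassium channel regulator ABCC9 (19.1-fold, 15.1-fold), JPH1 (19.3-fold, 6.39-fold), RAB40B (8.64-fold, 11.6-fold), IGFBP4 and PLAU. Genes that fell in both included LCN2, an iron-siderophore carrier (35.0-fold, 64.4-fold), CLIC3 (26.2-fold, 8.75-fold), the peptidase DPP4 (4.85-fold, 10.8-fold), CSRNP3 (4.60-fold, 14.9-fold), the proteoglycans HSPG2 (4.42-fold, 19.5-fold) and CSPG4 (4.25-fold, 7.14-fold), CRIP2 and LAMP3. CD44 and EGFR rose by sizes whose difference between the lines did not pass (0.15, adjusted p = 0.0619, and 0.02, adjusted p = 0.799). In number, 1577 genes rose in both lines and 1666 fell in both, against 1020.6 and 1079.2 for independent lists. Opposite changes were also above those values, with 1331 genes higher in DU145 and lower in PC3 (983.8 for independent lists) and 1589 the reverse (1119.6). Of 6163 genes called in both lines, 52.6% had the same sign, and across all 24128 genes the log2 changes had a Pearson r of 0.000 and a Spearman rho of 0.004, genes not being independent replicates.

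The difference between the lines in the resistant minus parental change was tested directly. On the log2 scale the PC3 change minus the DU145 change was -8.40 ± 1.61 for ABCB1 (adjusted p = 0.00191) and -7.57 for CDH1 (adjusted p = 1.07e-07). Genes that rose in DU145 and fell in PC3 with the largest differences were MTUS1 (532-fold up, 7.95-fold down; it overlaps PDGFRL), the protease inhibitor SERPINA1 (88.8-fold, 30.2-fold), MYH14, KIAA0040 (22.5-fold, 112-fold), DSP, the junctional protein CGNL1 (8.62-fold, 114-fold) and FAM110C (15.2-fold, 60.4-fold). In the other direction, TNS4 fell to no count in DU145 and rose 15.8-fold in PC3. CSF2 (112-fold down, 8.93-fold up), LHX1 (log2 changes -4.59 and 4.86), the apoptosis inhibitor BCL2A1 (56.7-fold, 6.68-fold), SCEL (2.91-fold, 61.2-fold), the carboxypeptidase CPA4 (2.57-fold, 43.7-fold) and IL24 went the same way. The difference passed for 10150 genes (42.1%), 5327 higher and 4823 lower in PC3, and 505 genes changed by at least 2-fold in opposite directions. With limma on log2(TPM + 1) over 15332 genes the split was 6685 against 3471 (65.8% higher, median of all genes 0.262), against 52.5% higher and a median of 0.034 with limma on log2(FPKM + 1) over the same genes. Of the lists, epithelial identity (median difference -2.36, camera adjusted p = 3.44e-13, and 0.00099 with an estimated correlation), NF-kB targets (-1.60, adjusted p = 1.54e-07, and 0.009) and mitochondrially encoded genes (-1.70, adjusted p = 2.56e-37, and 0.0061) differed by both tests.

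**Figure D4:**
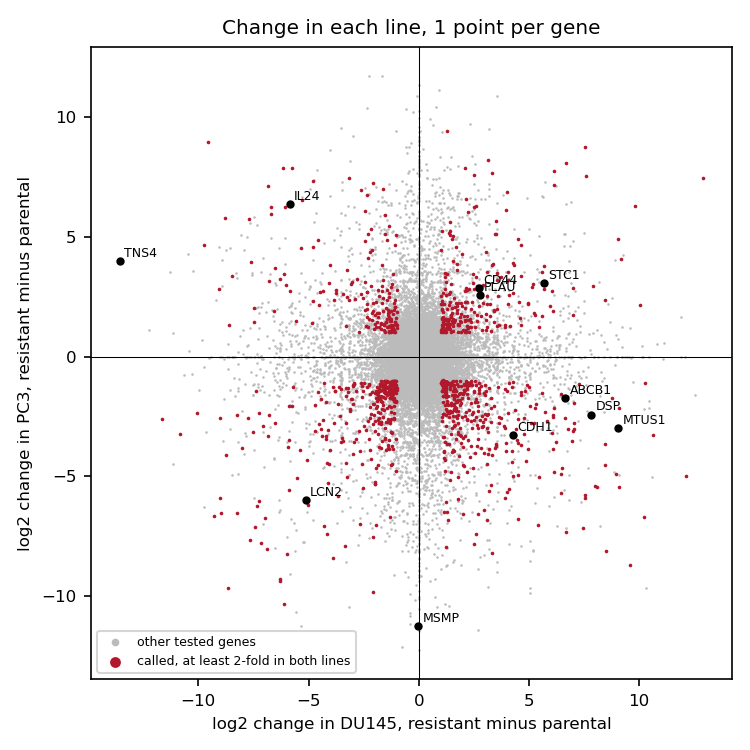
Log2 change (resistant minus parental) of each gene in DU145 on the horizontal axis against that in PC3 on the vertical axis, with genes called and changed at least 2-fold in both lines in red and a few named genes in black. Of 6163 genes called in both lines, 3243 lie in the quadrants of the same sign and 2920 in those of opposite sign, where CDH1 and DSP lie at 4.29 and -3.29 and at 7.83 and -2.43.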

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

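Of the tests in this part, those on 7q21 neighbours, on RUNDC3B and ABCB4, on nuclear genes for mitochondrial proteins and on other splits of the samples were chosen only after the results were seen. The results listed here stood out because the resistant minus parental change differed between the lines by a test of that difference, which held for 10150 genes and for 241 of the 275 named genes called in at least 1 line. Named genes were picked from the same data, in part for large or opposite changes. Their share is therefore no separate result beside the 42.1% of all genes. Among 50 splits drawn from 200 possible, the real split alone gave as many genes (1 of 50), with 10150 against a highest other count of 4167. The 8 other splits that kept the true groups of 1 line gave 2042 to 4167 genes and the 41 that kept neither gave 0. Every other split drawn thus mixed the groups of at least 1 line, which adds the gap between groups to the spread. The split that swaps the labels within 1 line was not drawn. The counts show that the libraries fall into their groups, and cannot say whether the difference arose by chance between single sublines.

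Epithelial genes rose in DU145 and fell in PC3, with a median difference of -2.36 over the list, -10.26 for DSP and -7.57 for CDH1. Cells of 1 line in cultures of the other are excluded as the source by the tables, since the 61 genes specific to PC3 stood at a median of 0.21% of their PC3 level in resistant DU145 (quartiles 0.061% and 1.388%) and the 40 specific to DU145 at 0.208% in resistant PC3 (0.101% and 0.298%). Of these, 10 of the 61 and 1 of the 40 stood above 10%, whereas cells mixed in would raise the whole set together. A trend with gene length was weak in both lines (Spearman rho -0.066 and -0.017), so its removal, which left the medians at 1.14 in DU145 (1.15 before) and -0.6 in PC3 (-0.61 before), had little to correct and tests little. The mesenchymal list gave no call for a difference between the lines (median difference -0.27, adjusted p = 0.9), with medians of -0.98 in DU145 (adjusted p = 0.0115, but 0.21 with an estimated correlation) and -1.1 in PC3 (adjusted p = 0.0891), so opposite positions between epithelial and mesenchymal states would rest on the epithelial list. A candidate explanation that stays open is that the sublines differ in epithelial state. DU145 is generally described as expressing CDH1, while the parental libraries held 3.81 CPM, a level not compared with other cultures of the line. The rises of CDH1 and DSP may in part reflect an atypical starting culture, which was not tested. No protein or morphology was analysed here to test a difference in epithelial state. Chance selection of clones that differed before treatment remains possible.

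ABCB1 rose in DU145 alone, with a difference between the lines of -8.4. A gain of the whole 7q21 region is argued against by the other 28 tested genes there, whose median change in DU145 was -0.4 (quartiles -0.87 and -0.06). With ABCB1 included 3 of the 29 rose, 2 of them by at least 2-fold, so a smaller gain of ABCB1 with adjacent genes is not addressed. The overlapping RUNDC3B and the paralog ABCB4 together held 3.17% of the CPM of ABCB1 in resistant DU145. This cannot decide on misassigned reads, since reads of these genes wrongly given to ABCB1 would be missing from their own counts. A gain limited to ABCB1 or shared with adjacent genes and a change at its promoter may each account for the rise, and none was tested.

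Mitochondrially encoded genes rose in DU145 and fell in PC3, with a median difference of -1.7. The PC3 list did not pass camera with an estimated correlation (adjusted p = 0.051) and the DU145 list did (0.0051), so by that test the fall is less certain than the rise. With limma after quantile normalization the medians went from -0.68 to -0.09 in PC3 and from 1.03 to 0.44 in DU145. That method sets values of equal rank equal, so changes of genes at the top ranks, MT-CO1 among them, are shrunk by construction. These medians therefore do not bear on how certain the fall is. RNA degradation that differed between groups is argued against by the correlation of the change with gene length across 12194 genes, with a Spearman rho of -0.066 in DU145 and -0.017 in PC3, genes not being independent replicates. A general change in mitochondrial content is argued against by 157 nuclear genes of the mitochondrial ribosome and respiratory chain, whose median change was 0.04 in DU145 (quartiles -0.12 and 0.28; 45 rose, 26 fell) and 0.09 in PC3 (-0.18 and 0.37; 58 rose, 34 fell). The mitochondrial ribosomal RNAs, looked at after the results were seen, made up 1.18% ± 0.12 (SD, n = 3) of counts in parental and 1.22% ± 0.06 in resistant DU145, so they did not follow the rise there, and 0.72% ± 0.06 and 0.36% ± 0.03 in PC3. This argues against an even rise of all mitochondrial transcripts in DU145, although oligo(dT) is not meant to capture ribosomal RNA. Changes in mitochondrial DNA copy number, in transcription or RNA stability, or in the capture of transcripts with oligo(dT) stay open.

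Other genes had differences, PC3 change minus DU145 change on the log2 scale, of -12.05 for MTUS1, -11.39 for SERPINA1, -11.38 for MYH14, -11.31 for KIAA0040, -9.95 for CGNL1, -9.84 for FAM110C, -0.41 for TUBB3 and -0.4 for VIM. Positive differences were 6.81 for CPA4, 7.47 for SCEL, 8.56 for BCL2A1, 9.45 for LHX1, 9.96 for CSF2 and 12.25 for IL24. TNS4 had a fitted difference of 17.52, which is no bound because resistant DU145 had no count. Of the lists, camera at its preset correlation also separated the lines for NF-kB targets (median -1.6, adjusted p = 1.54e-07, and 0.009 with an estimated correlation). Further lists passed at the preset correlation only, with medians of -1.34 for MHC class I presentation, 0.85 for unfolded protein stress, 0.67 for NRF2 and glutathione, 0.62 for 7q21 genes, 0.58 for microtubule-associated proteins, 0.52 for mitosis, 0.5 for S phase, -0.36 for cholesterol synthesis and -0.2 for hypoxia and glycolysis, or 0.04 with limma on log2(TPM + 1). Their adjusted p with an estimated correlation lay between 0.14 and 0.63.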

How the results depend on the processing

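Counts divided by 8, an FPKM filter of 1 within edgeR, the removal of mitochondrial genes and the other splits were chosen only after the data or the result were seen. Apart from the larger moves given below, counts under these and the other settings stayed within 1.5 times the reported ones, at 6409 to 10183 for DU145, 9499 to 11139 for PC3, 9125 to 10776 for the difference between the lines, 11791 to 14967 between parental lines, 1276 to 1733 higher and 1343 to 1857 lower in both, and 11 to 17 lists in DU145 and 9 to 16 in PC3. Counts divided by 8 gave 9822, 10679, 9886 and 13128 for the 4 comparisons, but among 16599 genes tested against 24128, so each is a larger share. Removing mitochondrial genes gave 9510, 10600, 10129 and 14505 among 24089. Requiring an FPKM of 5, which tests fewer genes, gave 6822 for PC3, 6565 for the difference, 7940 for the parental lines and 10 lists in DU145. Requiring a 2-fold change, a stricter threshold by construction, gave 3135, 4115, 5089 and 8667 genes, and 232 higher and 298 lower in both lines. List calls moved as well: with an estimated correlation 6 in DU145 and 3 in PC3, with fry 28 and 31, and in PC3 8 with limma on log2(FPKM + 5) and 7 under quantile normalization, for which the cause was not tested. Under quantile normalization MT-CO1 changed by 0.00 in PC3, against -0.67, because it holds the top rank in its libraries and that rank is set equal by construction.

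Leaving out each library in turn, which let the filter pass 25525 to 25590 genes, gave 8675 to 9570 genes in DU145, 9737 to 10633 in PC3, 9636 to 9875 for the difference, 13760 to 14671 between parental lines, 1458 to 1541 higher and 1511 to 1584 lower in both, and 15 to 17 lists in DU145 and 11 to 14 in PC3. Of 382 named calls, 373 remained with every library left out. Gene and list calls lost or gained in these fits may come from the changed set of tested genes, from fewer libraries or from the library itself, which were not told apart. Of 11277 values of named genes under alternatives, 11162 kept direction and side of the threshold, 94 lost the call, 20 gained it and 1 changed sign.

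With the replicate number as a block within each line the counts were 9047, 10183, 9685 for the difference, 1501 higher and 1593 lower in both, and 16 and 13 lists. The numbers did not pair the libraries, since deviations of same-numbered libraries correlated at -0.054, 0.016 and -0.013 in DU145 and -0.06, 0.077 and -0.11 in PC3.

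The 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 of 10 was as large as the real split, with 9554 genes against a highest other of 3 in DU145, 10615 against 4 in PC3 and 14561 against 0 between parental lines. For lists the values were 16 against 9 in DU145 and 13 against 8 in PC3. Every other split mixed the groups in unequal parts and so kept some of the true contrast. The lists it called at the preset correlation may be diluted real changes or false calls, which these splits cannot tell apart. For genes changed the same way in both lines, 1 of 50 splits gave as many, with 1577 higher against 2 and 1666 lower against 1. Neither chance nor sharing is tested by this, since splits that mix the groups of a line leave it almost without calls. Swapping the labels within DU145, a split not drawn, would count as higher in both the 1589 genes lower in DU145 and higher in PC3. It would count as lower in both the 1331 genes that went the other way. Depth limits genes near 0, such as ABCB1 in PC3, whose change was not detectable at this depth.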

Other observations

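The tests on chromosome windows were set before their results were seen, whereas the GO and KEGG terms were ranked without prior choice among 2841 tested. Ribosome biogenesis genes rose in both lines, with 65 of 102 higher and 12 lower in DU145 (median 0.31, camera adjusted p = 4.39e-05, but adjusted p = 0.58 with an estimated correlation) and 77 higher and 4 lower in PC3 (median 0.59, adjusted p = 2.16e-15, but 0.34). Proteasome genes of the KEGG term rose in 23 and fell in 2 of 42 in DU145 (median 0.18, adjusted p = 8.97e-04, but 0.64) and rose in 33 and fell in 5 in PC3 (median 0.52, adjusted p = 9.57e-10, but 0.35). Related GO terms were divided in DU145 by camera at the preset correlation. The proteasome core complex passed (adjusted p = 0.0119), while the proteasome complex (26 higher and 13 lower of 61, 0.261) and its accessory complex (0.615) did not. Nuclear pore genes rose in 51 and fell in 6 of 78 in PC3 (median 0.40, adjusted p = 1.23e-07, but 0.34). Genes of the COPII coat, which carries cargo out of the endoplasmic reticulum, fell in 12 and rose in 1 of 15 in DU145 (median -0.40, adjusted p = 4.44e-04, but 0.46). At the preset correlation 130 terms were called in DU145 and 351 in PC3, and 0 in either with an estimated correlation.

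Neighbouring genes changed together along some chromosomes. Of 539 windows of 25 neighbouring genes, 36 in DU145 (18 higher, 18 lower) and 68 in PC3 (38 higher, 30 lower) had a median change of at least 0.5 log2 units, against a median of 1 and a highest of 5 in 1000 permuted gene orders for DU145 and of 3 and 10 for PC3. In DU145 they included 5 higher windows on chromosome 13 (0.69 to 0.96, between 19633659 and 52033600), followed there by 2 lower ones (-0.94 and -0.53, between 52024691 and 97469128). The DU145 windows also included 9 lower on chromosome 3 (-0.68 to -0.5, between 3126933 and 51389397). Higher ones were 4 on chromosome 6 (0.5 to 0.68, between 6144084 and 32859851) and 2 on chromosome 14 (0.59 to 0.79, between 22766522 and 24379604). In PC3 they included 15 higher windows on chromosome 1 (0.5 to 0.87, between 6590724 and 120176520), 7 higher on chromosome 16 (0.52 to 0.84, between 48356364 and 85688954) and 8 lower on chromosome 6 (-0.77 to -0.51, between 26251651 and 49493107). As a hypothesis, these counts are consistent with altered copy number or regional regulation of chromosome segments in the sublines, which expression alone does not separate. A window over the protocadherin cluster on chromosome 5 (140926299 to 141512981), a family whose members share sequence, had a median of 1.61 in DU145 and -2.59 in PC3. The chromosome 6 window from CFB to TAP1, the latter in the MHC class I list, had a median of 0.68 in DU145 and -0.51 in PC3.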
